A study of Streptomyces hygroscopicus subsp. jinggangensis 5008 with 2 samples.

How the data were processed

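RNA of mycelia was sequenced from 2 strains of Streptomyces hygroscopicus subsp. jinggangensis, a soil bacterium that makes the antifungal validamycin. The strains were the wild type and a double mutant of shbR1 and shbR3, each grown for 48 h at 37 °C in shaken fermentation medium, with 1 library per strain. Total RNA was extracted with TRIZOL and libraries followed a TruSeq RNA protocol, per the labels' protocols. The molecule label reads polyA RNA, and rRNA genes held 28.9% of the reads of the wild type library and 24.6% of those of the double mutant library.

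The deposited table gives each gene's RPKM (reads scaled to gene length and library size) in both libraries, and the authors' fold ratio, p-value and FDR, per the file headers. CASAVA 1.8 and TopHat2 2.0.6 are named in the submitters' processing notes. Those notes list the mouse build mm10, whereas the table places its genes on a Streptomyces chromosome and 2 plasmids, so coordinates are those of the table. The read counter, the use of strand and the statistical test are not given in the sources used here, and overlapping or antisense genes cannot be told apart. From the second to the sixth column the header is shifted by 1 name against the cells, and the cells were read by content. The RPKM column of the double mutant carries its abbreviation. The other column carries a code that the labels do not explain. It was taken as the wild type because the series design names only the parent strain and the mutant as compared, and every direction below rests on that reading.

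The deposited RPKM values of 0.00001 stand for 0 and were set to 0. RPKM times gene length was a whole multiple of the worth of 1 read within 0.001 reads for 100% of genes in both libraries, so the reads behind each value were recovered. The wild type library held 1426185 reads, of which 1270312 lay in genes, and the double mutant library 1933590 and 1738740. The median gene had 13 and 15 reads, 237 and 164 genes had 0 reads, and 3785 and 3377 genes had under 10. The limit that 0 reads allows was taken as 3 reads, which for a gene of 1 kb is 2.10 RPKM in the wild type library and 1.55 RPKM in the double mutant library.

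Ratios were computed as log2 of RPKM plus a pseudocount of 1, double mutant over wild type, a scale that understates differences of low genes. Folds given with an interval are ratios of RPKM without a pseudocount. Their 95% intervals are exact conditional binomial (Clopper-Pearson) intervals on the recovered reads, and intervals and limits cover counting error only. Genes with a mean of at least 1 RPKM passed the filter. With 1 library per group there is no replicate check, so no difference reported here rests on a p-value across genes, and genes were counted by a rule of size of at least 2-fold. The plan made before the data were examined had foreseen a table of counts or of a normalized unit, and the rules for a normalized unit were used.

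Before the data were examined, 29 gene lists were fixed by product name. Each list with at least 5 members past the filter was set against 10000 random lists of the same size matched on mean expression in 10 bins, and it was said to stand apart when its median lay outside their 2.5th to 97.5th percentiles. This describes these libraries alone. A validamycin list found 1 member by name, so the 10 genes on each side of that member were used, a choice made after the table was seen, in place of those around the valiolone synthase gene, which the table does not name. The terpene list also took 7 phosphopantetheine genes by their names. Runs were at least 4 adjacent genes, all at least 2-fold in the same direction, and their number was set against 100 shuffles of the calls over gene positions. Lists of nitrogen source uptake and universal stress genes were added after the data were seen, so they are given as counts without a percentile. To set the authors' deposited p-values beside the reads, Fisher's exact test was run on the recovered reads of each gene against all others, with Benjamini-Hochberg adjustment, as a comparison of these 2 libraries only.

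Genes were named by a rule fixed in advance. It took the receptor and synthase genes of butyrolactone signalling, the 8 highest and 8 lowest log2 ratios among genes with a mean of at least 10 RPKM, up to 2 highest and 2 lowest members of each list, and the first 3 longest runs in each direction, with runs of equal length taken in order of position. Any other gene or stretch named below was chosen after its values were seen, and this holds for the boundaries of the stretch SHJG_0271 to SHJG_0327.

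The alternatives fixed in advance were scaling to reads in genes, median of ratios, upper quartile and scaling without the 10 most abundant genes; no filter or a mean of at least 10 RPKM; pseudocounts of 0.5 and 5; the authors' deposited fold ratios; thresholds of 1.5-fold and 4-fold; only genes whose interval excludes 1; random lists without matching; list means; and runs of at least 3 genes. The settings added after the data were seen were a trimmed mean of ratios, scalings without structural RNA or without the stretch, a mean of at least 10 reads, and lists thinned of neighbours, of the stretch or of BldK genes. In lists thinned of neighbours, each group of neighbouring members was given its mean, matched on the expression of its first member. The random lists set against these were drawn from single genes and not from means of groups, so the 2 sides are not fully alike. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. On data simulated for this comparison over 9086 genes, the changed genes were drawn from those with a mean of at least 5 reads. The rule of size recovered 93% of 100 genes set 3-fold apart and 100% of 100 set 8-fold apart, and recovery of genes with fewer reads was not tested. In that simulation 97.0% of intervals held the true fold, and 4.5% of 200 unchanged lists fell outside the central range. Those lists were random draws of genes with independent counting noise, so lists of neighbouring genes that move together were not tested.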

Results

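The transcriptome of mycelia was compared between the wild type strain and a double mutant of shbR1 and shbR3, with 1 library of each strain after 48 h of culture. The table held 9086 genes, 3249 of them annotated as hypothetical proteins. The wild type library had 1426185 reads and the double mutant library 1933590, and the median gene had 13 and 15 reads. There is no replicate check of any difference below, and each describes these 2 libraries. The column taken as wild type was matched by elimination, since its code is not explained in the labels, and all directions rest on that match.

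The targeted genes were looked up first. The table gives no gene symbols and pairs no locus with shbR1 or shbR3, so receptors of gamma-butyrolactones, the small signalling molecules of streptomycetes, were read by product name. The receptor gene SHJG_4003 was 6.78-fold lower in the double mutant library (95% interval 1.92 to 36.5), with 3 reads against 15. The gene SHJG_4000, with the same annotation, was 2.63-fold higher (1.90 to 3.70), with 171 reads against 48. The binding protein gene SHJG_8325 was 2.26-fold lower (1.81 to 2.83) and the receptor gene SHJG_8651 1.43-fold lower (1.17 to 1.75). The A-factor receptor-like gene SHJG_7144 had 78 reads against 64, a fold of 0.899 (0.638 to 1.27). None of these 5 genes was at 0 reads in the double mutant library, and without a pairing of loci and symbols these values do not check the labels. Of the synthesis genes, SHJG_7319 was 2.40-fold higher (1.23 to 5.03) and SHJG_4004 had 6 reads against 4. The 7 genes of this list had a median log2 ratio of -0.15, at percentile 58.7 of random lists.

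The double mutant library held more reads of a chromosomal stretch around a validamycin synthesis gene, of nitrogen assimilation genes, of secreted protease genes and of the genes annotated as the peptide importer BldK. It held fewer reads of respiratory chain genes, most of the 2-fold lower ones being NADH dehydrogenase genes. Fewer reads also came from single stretches of gas vesicle genes and of central carbon genes such as those of succinate dehydrogenase and transaldolase. Of 8921 genes past the filter, 893 were at least 2-fold higher in the double mutant library and 1380 at least 2-fold lower. The counting interval excluded 1 for 494 of the higher and 836 of the lower genes. Reads redrawn with no difference between the libraries gave a mean of 980.3 genes past 2-fold, and 129.8 whose interval also excluded 1, over 100 draws. The median log2 ratio of all genes was -0.19, and it lay between -0.35 and 0.072 under the other scalings, turning above 0 under 3 of them. The share of the 2-fold genes that were higher, 39.3%, became 54.6% with median of ratios scaling, 51.1% with upper quartile scaling and 53.0% with a trimmed mean of ratios. It was 29.1% with structural RNA left out of the scaling, 59.3% without the stretch described next and 59.6% without both.

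**Figure D1:**
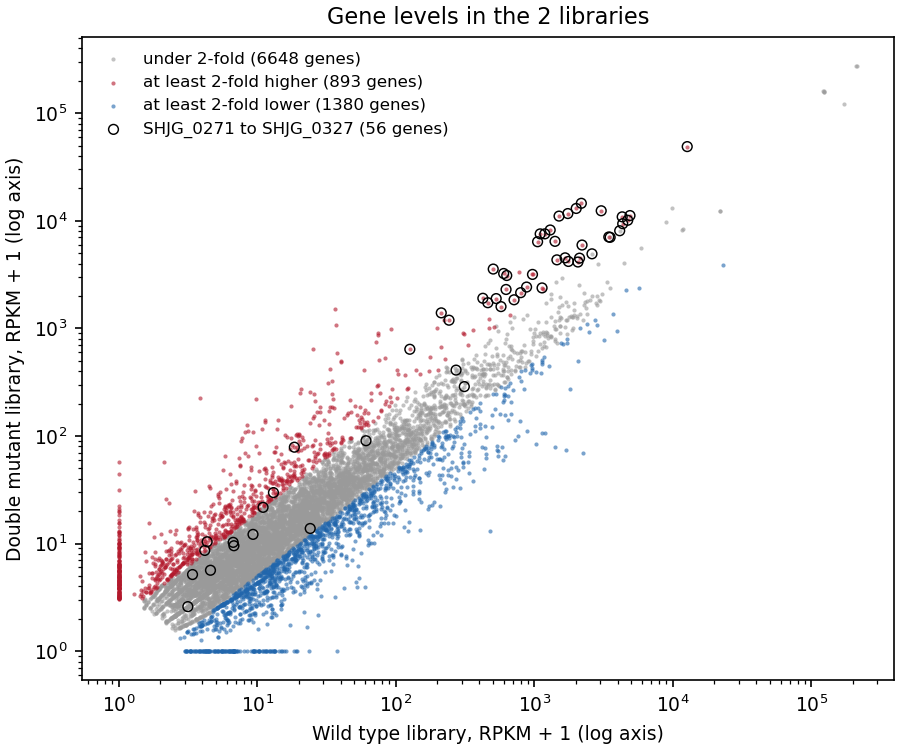
Level of each gene past the filter in the wild type library (horizontal axis) and in the double mutant library (vertical axis), as RPKM plus 1 on log axes, 1 point per gene. Red points are the 893 genes at least 2-fold higher, blue points the 1380 at least 2-fold lower, and black rings the 56 genes of SHJG_0271 to SHJG_0327, which lie mostly above the other genes of similar level.

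The stretch from SHJG_0271 to SHJG_0327, at 361127 to 431887 on the chromosome, took 22.6% of all reads in the double mutant library and 7.27% in the wild type library. Of its 56 genes, 42 were at least 2-fold higher and 0 at least 2-fold lower. Validoxylamine synthase (SHJG_0274), an enzyme of validamycin synthesis, had 10106 RPKM against 4729, a fold of 2.14 (2.09 to 2.19). Of the 15 genes SHJG_0271 to SHJG_0285 around it, annotated among others as cyclase, cyclitol kinase, nucleotidylyltransferase and glycosyltransferase, 13 were at least 2-fold higher, with a pooled fold of 2.27 (2.25 to 2.29). In the window of 10 genes on each side of SHJG_0274, 12 of 21 genes were higher and 1 was lower. The 13 genes SHJG_0286 to SHJG_0298 had a pooled fold of 1.20 (1.06 to 1.34) on 762 reads against 470, with 3 at least 2-fold higher, 0 lower and a median log2 ratio of 0.57. The most abundant of them, the tellurium resistance gene SHJG_0290, had a fold of 0.919 (0.777 to 1.09), and the hypothetical gene SHJG_0295 was 4.43-fold higher (1.29 to 23.5) on 18 reads against 3.

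All 19 genes from SHJG_0300 to SHJG_0318 were higher, with a pooled fold of 5.47 (5.40 to 5.55), and this was the longest run of adjacent higher genes. They include the 3-oxoacyl-ACP synthase genes SHJG_0306, 4.56-fold higher, and SHJG_0308, 6.35-fold higher, the isobutylamine N-hydroxylase gene SHJG_0314, 6.05-fold higher, and the short-chain dehydrogenase gene SHJG_0303, 7.33-fold higher. The 9 genes SHJG_0319 to SHJG_0327 followed with a pooled fold of 2.51 (2.46 to 2.56). In that part the SARP-family regulator gene SHJG_0322, of a family that switches on antibiotic gene clusters, was 2.75-fold higher (2.54 to 2.98).

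**Figure D2:**
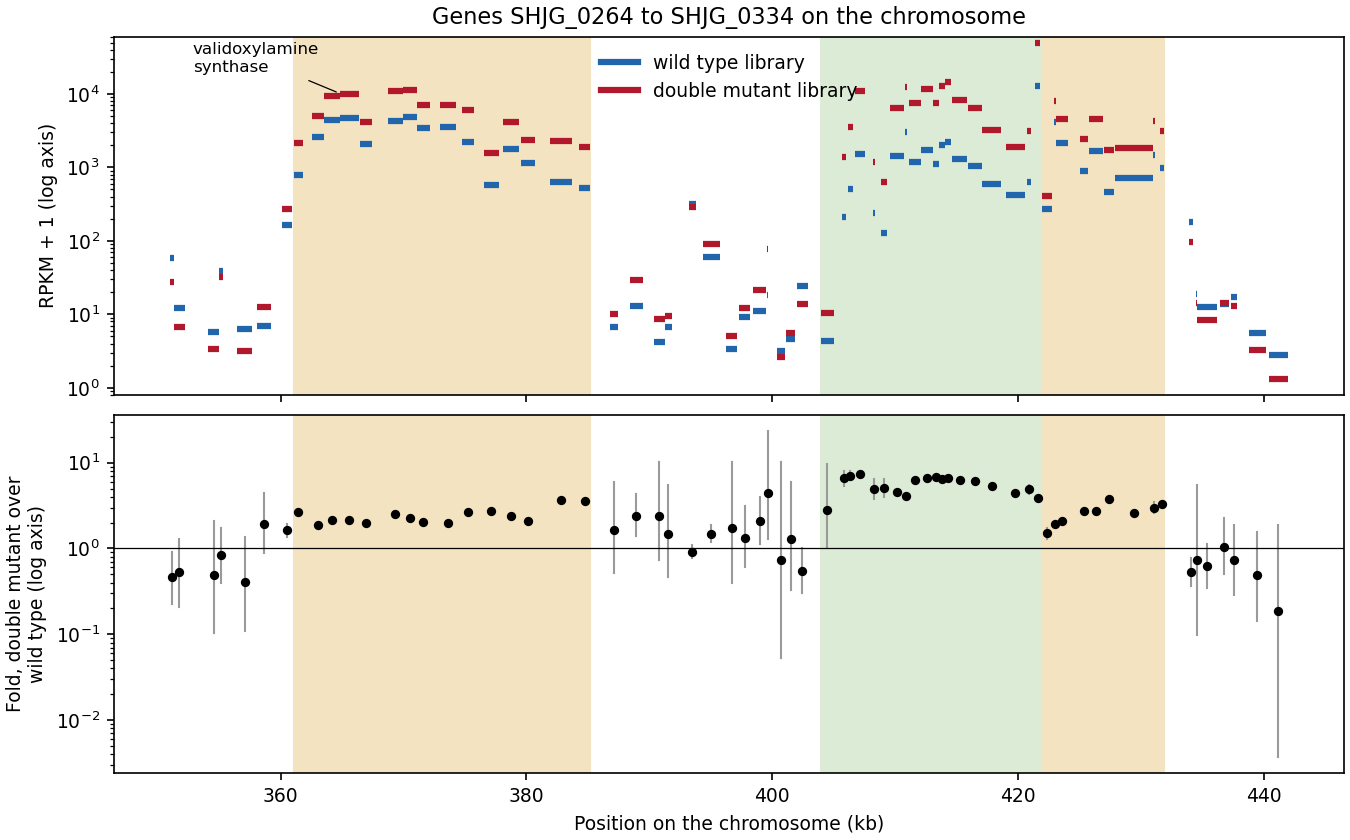
Genes SHJG_0264 to SHJG_0334 by position on the chromosome in kb. The upper panel shows RPKM plus 1 on a log axis in the wild type library (blue) and the double mutant library (red), each bar spanning a gene; the lower panel shows the fold on a log axis with its 95% counting interval, for genes with reads in both libraries. Shaded from left to right are SHJG_0271 to SHJG_0285 (pooled fold 2.27), SHJG_0300 to SHJG_0318 (5.47) and SHJG_0319 to SHJG_0327 (2.51).

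Nitrogen assimilation genes were higher as a list. Of 36 members, 20 were at least 2-fold higher and 3 lower, and the median log2 ratio of 1.30 lay above all 10000 random lists. With 1 value per group of neighbouring members the median was 0.74, also above all of them. The P-II regulatory protein gene SHJG_6705, whose product senses nitrogen status, was 43.3-fold higher (26.9 to 74.6), and the ammonium transporter gene SHJG_6704 next to it was 29.7-fold higher (23.4 to 38.3). All 6 urease genes SHJG_2665 to SHJG_2670 were higher, with a pooled fold of 11.3 (9.34 to 13.8) on 1732 reads against 113. The lowest members were NAD-glutamate dehydrogenase (SHJG_4463), 6.27-fold lower (5.57 to 7.07), and the ornithine acetyltransferase gene SHJG_3011 of arginine synthesis, 3.26-fold lower (2.55 to 4.19).

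Secreted protease genes were also higher as a list, with 19 of 52 members at least 2-fold higher, 2 lower and a median log2 ratio of 0.76, above all 10000 random lists. The neutral zinc metalloprotease gene SHJG_6527 was 11.7-fold higher (10.02 to 13.7) and the subtilisin-type peptidase gene SHJG_0689 8.24-fold higher (5.37 to 13.2). In the glycoside hydrolase list 15 of 93 members were higher and 6 lower (median 0.16, percentile 99.9). The glycosyl hydrolase gene SHJG_1869 was 4.06-fold higher (3.66 to 4.51), and the cellulase gene SHJG_4626 was 6.67-fold lower (3.64 to 13.2).

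The list of morphology genes, which act in aerial growth and sporulation, had 15 of 36 members higher and 3 lower (median 0.40, percentile 99.9). Its 10 members annotated as BldK, an oligopeptide importer needed for aerial growth, were all higher, and without them the median was 0.14 at percentile 93.6. With 1 value per group of neighbouring members it was 0.096 at percentile 90.3. The BldKB gene SHJG_6217 was 10.7-fold higher (9.33 to 12.2), and the run SHJG_6208 to SHJG_6218 had a pooled fold of 8.69 (7.85 to 9.63). The BldB regulator gene SHJG_6822 was 2.77-fold lower (2.24 to 3.44) and the WhiB gene SHJG_0394 2.71-fold lower (1.55 to 4.90). In the fatty acid synthesis list 9 of 30 members were higher and 2 lower (median 0.30, percentile 98.8), and the counting interval excluded 1 for 4 of the higher and 1 of the lower. Of the members, 3 lie in the stretch above, and without these the median was 0.11 at percentile 88.3. It was 0.10 at percentile 88.9 at a mean of at least 10 RPKM, and 0.047 at percentile 82.2 with 1 value per group of neighbours.

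Respiratory chain genes were lower as a list, with 20 of 37 members at least 2-fold lower, 1 higher and a median log2 ratio of -1.29, below all 10000 random lists. With 1 value per group of neighbouring members, 14 values in all, the median was -0.86 at percentile 0.49. Lower members were 14 of 15 genes of NADH dehydrogenase, the proton-pumping entry complex of the chain, 4 of 9 ATP synthase genes and 2 of 13 cytochrome genes, and the difference between these parts was not tested. NADH dehydrogenase subunits K (SHJG_5714) and I (SHJG_5712) were 6.78-fold (4.92 to 9.52) and 5.72-fold (4.84 to 6.80) lower. The run SHJG_5704 to SHJG_5718 of 15 genes was 4.72-fold lower when pooled (4.49 to 4.96).

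In the list of glycolysis and the pentose phosphate pathway, 9 of 35 members were lower and 0 higher (median -0.62, percentile 0.77). With 1 value per group of neighbouring members the list lay within the random lists (median -0.29, percentile 36.6, 24 values), and 5 of the 9 lower members lie in the run SHJG_7571 to SHJG_7577. In that run transaldolase (SHJG_7576) was 8.57-fold lower (7.17 to 10.3) and 6-phosphogluconate dehydrogenase (SHJG_7572) 7.91-fold lower (6.78 to 9.28). The tricarboxylic acid cycle list as a whole lay within the random lists (median -0.29, percentile 44.1), with 4 of 23 members lower. Among these were the adjacent succinate dehydrogenase genes SHJG_7881, 23.1-fold lower (20.4 to 26.2), and SHJG_7882, 32.4-fold lower (26.5 to 39.95).

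All but 1 of the 8 gas vesicle genes were at least 2-fold lower (median -1.91, below all 10000 random lists), with SHJG_7460 10.2-fold lower (4.32 to 29.2) and SHJG_7458 6.42-fold lower (3.88 to 11.2). They all lie between SHJG_7457 and SHJG_7466. Chaperone genes had 5 of 30 members lower and 1 higher (median -0.58, percentile 1.66), with the heat shock protein gene SHJG_4359 4.57-fold lower (3.55 to 5.93). The chaperone list lay outside the random lists in 13 of 17 alternatives. Many of these were scalings, which shift all genes nearly alike and so could hardly move a list among random lists. The chaperone list lay within the random lists at a mean of at least 10 RPKM (percentile 5.15) and with a pseudocount of 5 (4.76). It also did so with list means (6.53) and with 1 value per group of neighbours (19.9). Of 204 transposase and integrase genes, 50 were lower and 18 higher (median -0.46, below all 10000 random lists). The counting interval excluded 1 for 14 of the lower and 2 of the higher, and copies of mobile elements can share reads.

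Several of the genes farthest from equal levels lie in these groups. Among genes with a mean of at least 10 RPKM, the highest log2 ratio was that of the 2OG-Fe(II) oxygenase gene SHJG_8735, 79.3-fold higher (30.7 to 292.3), near the xanthine/uracil permease gene SHJG_8737, with 136 reads against 2 (50.2-fold, 13.6 to 418.3). The hypothetical gene SHJG_1315 was 26.3-fold higher (20.001 to 35.2). The others of the 8 highest were the tRNA genes SHJG_t48 and SHJG_t27 and the hypothetical gene SHJG_7132, with 0 reads in the wild type library against 8, 6 and 7. Set against the limit of 3 reads they were at least 1.97-fold, 1.48-fold and 1.72-fold higher, but the counting intervals start at 1.26, 0.868 and 1.06, so that of SHJG_t27 includes 1. At the low end, the cytochrome b subunit gene SHJG_7880 beside the succinate dehydrogenase genes was 18.0-fold lower (14.7 to 22.2) and the sigma factor gene SHJG_2108 19.8-fold lower (8.11 to 62.8). The neighbours SHJG_7883 and SHJG_7884 had 3 reads against 88 and 1 read against 24, folds of 0.0251 (0.00509 to 0.0759) and 0.0307 (0.000747 to 0.188). The hypothetical genes SHJG_2102 and SHJG_1220 had 0 reads in the double mutant library against 7 and 4. Set against 3 reads they were at least 3.16-fold and 1.81-fold lower, but the counting intervals start at 1.95-fold and 0.895-fold lower, so that of SHJG_1220 includes 1.

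Regulator families did not stand apart as lists in the main setting, though TetR-type regulators did at a mean of at least 10 RPKM (median -0.52, percentile 0.12). Medians lay within the random lists for AraC-type regulators (-0.28, percentile 20.9), TetR-type regulators (-0.31, percentile 8.05), SARP and LuxR regulators (-0.11, percentile 63.2), sigma factors (-0.29, percentile 20.1) and 2-component systems (-0.11, percentile 79.0). AdpA (SHJG_4295), the central activator downstream of butyrolactone signalling in streptomycetes, had 786.8 RPKM against 626.3, a fold of 1.26 (1.16 to 1.36). The AraC-type gene SHJG_1554 was 3.26-fold higher (3.004 to 3.54). The same held for ribosomal proteins (-0.51, percentile 5.82), aminoacyl-tRNA synthetases (-0.37, percentile 25.5), oxidative stress (-0.27, percentile 43.2), sugar transport (0.11, percentile 96.5) and cell division and wall (-0.09, percentile 80.0). It held too for polyketide and peptide synthases (0.019, percentile 77.7), terpenes (-0.0036, percentile 81.4), iron uptake (-0.40, percentile 10.4) and phosphate (-0.06, percentile 68.0). Amino acid synthesis (-0.07, percentile 80.3) lay within the random lists as well. So did the 18 rRNA genes (-0.63, percentile 8.09), though these are copies of 5S, 16S and 23S genes, and the classes differed in direction. Single members still stood apart, such as catalase/peroxidase (SHJG_8260), 4.24-fold higher (4.06 to 4.42), the NRPS gene SHJG_1132, 5.64-fold higher (4.62 to 6.96), and argininosuccinate lyase (SHJG_2994), 4.01-fold lower (3.24 to 4.99). In all, 10 of 28 lists stood outside the central 95% of random lists, 5 above and 5 below, against 1.4 by chance if members were independent. With 1 value per group of neighbouring members 5 lists stood apart, those of nitrogen assimilation, secreted proteases, glycoside hydrolases, respiration and transposases, and gas vesicle genes had too few values.

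**Figure D3:**
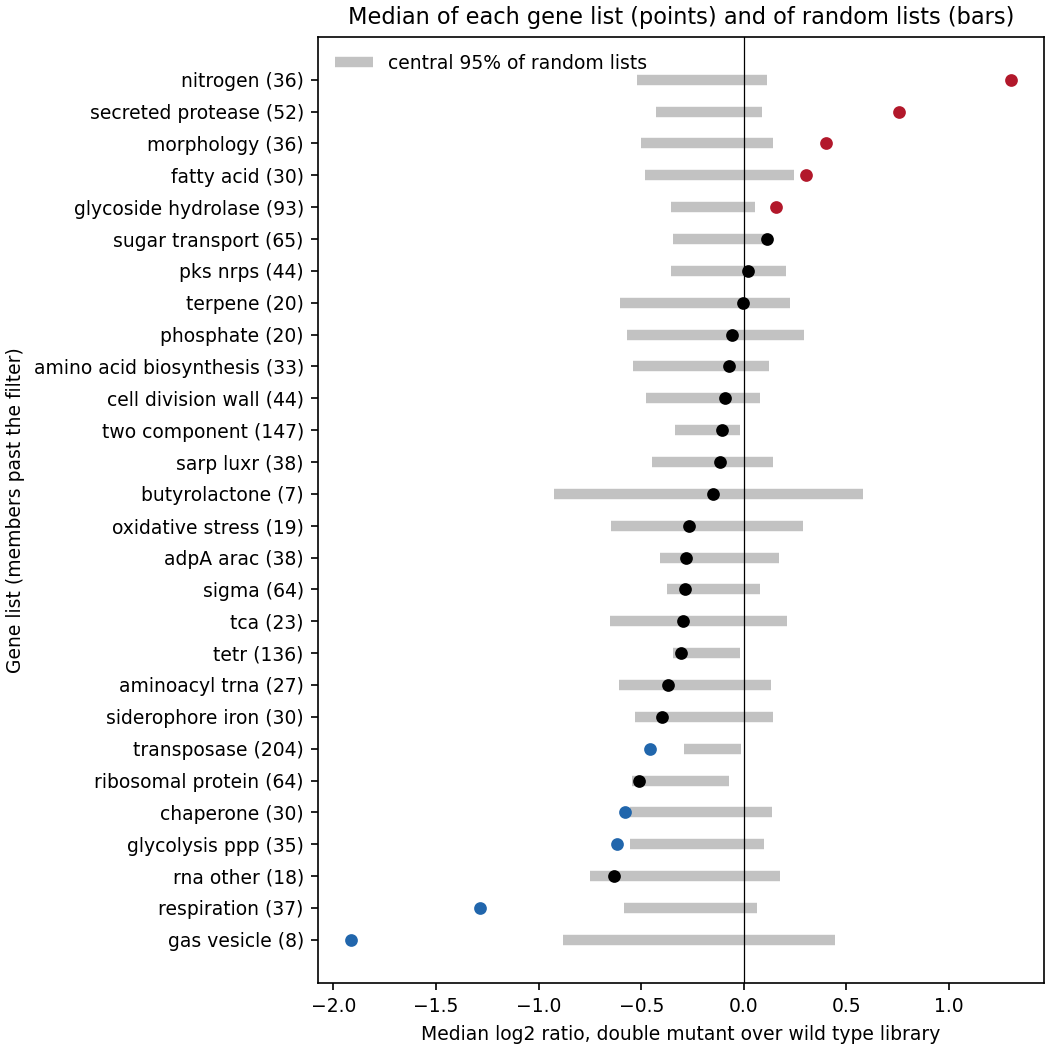
Median log2 ratio of each of the 28 gene lists (points; members past the filter in parentheses) and the central 95% of the medians of 10000 random lists matched on expression (grey bars). Red points lie above and blue points below the bars, with nitrogen assimilation at 1.30 and gas vesicle genes at -1.91 at the ends.

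Neighbouring genes often lay on the same side. There were 29 runs of higher genes, with 171 genes, and 41 runs of lower genes, with 245 genes; shuffled positions gave at most 3 and 11 runs. Higher runs outnumbered lower ones under 5 other scalings. These gave 40 against 29 by median of ratios, 35 against 31 by upper quartile and 37 against 30 by a trimmed mean. They gave 42 against 26 without the stretch SHJG_0271 to SHJG_0327 and 42 against 25 without that stretch and structural RNA. Lower runs stayed more numerous when scaled to the reads in genes (28 higher, 43 lower) and without the 10 most abundant genes (24 higher, 51 lower). Behind the runs of 19 and 11 genes named above, the third longest of higher genes were 2 runs of 8 genes each. In SHJG_2827 to SHJG_2834, annotated among others as choline oxidase, betaine aldehyde dehydrogenase and sarcosine dehydrogenase, the pooled fold was 3.94 (3.13 to 4.99). In SHJG_7324 to SHJG_7331 it was 10.1 (6.44 to 16.9), on 275 reads against 20. The longest run of lower genes was SHJG_2450 to SHJG_2466, with 17 genes that include acetoin and branched-chain keto acid dehydrogenase subunits, 3.80-fold lower when pooled (3.42 to 4.23). The third, SHJG_8790 to SHJG_8799, held 10 genes and was 2.77-fold lower (2.52 to 3.03).

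The authors' deposited table calls 1870 genes at an FDR under 0.05, 445 with a fold above 1 and 1425 with a fold below 1. The RPKM columns sum to 2132486 in the double mutant and 1877352 in the wild type library, a ratio of 1.14. Fisher's exact test on the recovered reads, which compares these libraries and not the strains, called 1824 genes at a Benjamini-Hochberg adjusted p under 0.05. Of these, 1427 are also called in the authors' deposited table and 397 are not, 242 of the latter higher, while 443 genes are called in the authors' deposited table alone. With at least 2-fold added, the authors' deposited table leaves 362 higher and 808 lower genes. Of the genes called in the authors' deposited table, 267 have a counting interval on the recovered reads that includes 1, and 243 of these are shorter than 500 bp. A fold above 1000 is given for 237 genes in the authors' deposited table, and the largest there, 5.59e+06, belongs to a gene with 8 reads against 0.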

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

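The trimmed mean, the scalings without structural RNA or the stretch SHJG_0271 to SHJG_0327, the filter on reads and the thinned lists were chosen after the data were seen. The median log2 ratio of all genes, -0.19, was 0.0064 with median of ratios scaling, -0.036 with upper quartile scaling, -0.32 without the 10 most abundant genes, -0.012 with a trimmed mean, -0.35 without structural RNA, 0.067 without the stretch and 0.072 without both. These values follow from the scaling factors themselves. Against 2273 genes past 2-fold (893 higher, 1380 lower), there were 1238 (459 and 779) at a mean of at least 10 RPKM, 1254 (470 and 784) with a pseudocount of 5, 4356 (1707 and 2649) at 1.5-fold and 603 (274 and 329) at 4-fold. There were 1330 (494 and 836) with an interval excluding 1 and 1237 (473 and 764) at a mean of at least 10 reads. Lower genes numbered 895 without the stretch in the scaling and 890 without the stretch and structural RNA. Without the 10 most abundant genes in the scaling the balance moved the other way, to 748 higher and 1699 lower genes. Against 29 runs of higher and 41 of lower genes, there were 60 and 129 at 1.5-fold and 56 and 82 at 3 genes a run. Higher and lower runs numbered 23 and 25 at 10 RPKM, 24 and 26 with a pseudocount of 5, 40 and 29 with median of ratios and 35 and 31 with upper quartile. They numbered 37 and 30 with a trimmed mean, 24 and 51 without the 10 most abundant genes, 42 and 26 without the stretch in the scaling and 42 and 25 without the stretch and structural RNA. Stricter or looser rules admit fewer or more genes by construction; for the rest the cause was not tested.

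With 1 value per group of neighbours, 5 of the 10 lists stood apart: nitrogen, secreted protease, respiration, transposase and glycoside hydrolase. That setting leaves gas vesicle genes with too few values, and chaperone, glycolysis, morphology and fatty acid lists fell within the random lists. The scalings shift all genes nearly alike, so they could hardly move a list among the random lists. Lists within the random range stood apart in 8 cases. Sugar transport lay above it under 4 settings (no filter, 10 RPKM, unmatched lists, means). Below it lay TetR at 10 RPKM, ribosomal protein and rRNA with unmatched lists, and the tricarboxylic acid cycle with means. None of the 10 lists changed the sign of its median under any setting run. The scalings could not have turned the sign except for glycoside hydrolases (median 0.16), as the other medians were larger than the shifts. Of 102 named genes past 2-fold, 73 stayed past it in all 13 settings run for genes. The settings that change only the filter leave a gene's ratio as it was. No sign changed, but none of these settings could turn the sign of a gene past 2-fold. Depth limits the low genes most, since 3785 genes had under 10 reads in the wild type library. No paired analysis was possible because each group has 1 library.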

Other observations

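All tests and added lists here were chosen after the results they concern were seen, apart from values of the fixed lists. Of 70 genes for the uptake of amino acids, peptides and nucleobases outside the fixed nitrogen list, 28 were at least 2-fold higher and 4 lower, with a median log2 ratio of 0.73. This list was written after some of its members had been seen to be higher, among them BldK and permease genes, so its count is no independent evidence of a direction. The stretch SHJG_7318 to SHJG_7331 which holds the butyrolactone synthesis gene SHJG_7319, had 12 of 14 genes higher and a pooled fold of 4.40 (3.57 to 5.47) on 621 reads against 104. In it the TylR-like regulator gene SHJG_7324 had 57 reads against 2, a fold of 21.0 (5.56 to 177.8).

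Of 13 universal stress protein genes, 8 were at least 2-fold lower and 0 higher, with a median log2 ratio of -1.05, a list likewise written after runs that hold members of it had been seen. Some of them lie in the stretch SHJG_8762 to SHJG_8799, where 33 of 37 genes were lower and the pooled level was 2.47-fold lower (2.34 to 2.59). Hydrogenase, potassium uptake and V-type ATPase genes are annotated in that stretch. The genes of plasmid p2 had a median log2 ratio of 0.39, with 55 of 75 above the chromosome's median of -0.19, and those of plasmid p1 had a median of -0.11.

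The stretch SHJG_0271 to SHJG_0327 was higher in the double mutant library in 42 of 56 genes. The 9 scalings do not account for this, since the lowest median log2 ratio of the stretch over them was 1.25. They lower log2 ratios by about 0.18 at most, too little to bring the stretch below 2-fold, so this covers these scalings only. A gain in copies of the whole stretch was first tested by the number of its genes with an interval wholly below 2-fold. The most favourable scaling was used, and more than 5 such genes were set as the bound to exclude a gain. The count was 2, so this test leaves a gain in copies open, and most single genes between the abundant parts have too few reads to decide. Pooled, the 13 genes SHJG_0286 to SHJG_0298 had a fold of 1.20 (1.06 to 1.34) before that scaling, with 3 of them at least 2-fold higher. A 2-fold gain that raised all these genes alike would not give that pooled fold, but 1 library per strain does not settle the question. A test added after the count of 2 was seen set the parts against each other. The pooled fold of SHJG_0300 to SHJG_0318 was 2.41 times that of SHJG_0271 to SHJG_0285 (2.36 to 2.47). A gain in copies that raised all genes of the stretch alike would need equal folds, which these parts lack. A gain to which the parts responded in different degrees would not need them, so this test leaves that open. The parts were also delimited by their levels in these same libraries, so unequal folds were partly built into the choice. The bounds cover counting error only. Loss of shbR1 and shbR3 stays a possible explanation that cannot be told apart from other differences between the cultures with 1 library per group.

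The authors' deposited p-values below 1 were reproduced by a test on RPKM, and few of them by the same test on reads. Fisher's exact test on RPKM rounded up to whole numbers, with the RPKM sums of 2132486 and 1877352 as totals, gave 100% of the 7712 p-values below 1 in the authors' deposited table within 1%. The same test on the recovered reads gave 1.04% of them. A read in a gene of 517 bp in the double mutant library, or 701 bp in the wild type library, is worth 1 RPKM, so shorter genes enter such a test with more than their reads. Such a test sees no difference at an RPKM ratio of 1.14, so that genes at equal RPKM count to the lower side. The authors' deposited table calls 29.9% of genes under 500 bp and 17.8% of genes of at least 2000 bp, while Fisher's exact test on reads with Benjamini-Hochberg adjustment, at the same threshold, calls 15.2% and 32.6%.

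The median gene was lower in the double mutant library, at a log2 ratio of -0.19. Whether reads taken by the stretch SHJG_0271 to SHJG_0327 account for this cannot be told apart from other causes. The median was 0.067 with the stretch left out of the scaling, but that step shifts all genes alike by an amount set by the shares of reads, and median of ratios scaling, which keeps the stretch, gave 0.0064. More reads of rRNA, tRNA and miscRNA do not account for it, since rRNA genes held 24.6% of the reads in the double mutant library against 28.9%, and leaving these RNAs out moved the median to -0.35. The rRNA classes differed in direction. In the double mutant library 23S genes held 8.02% of the reads against 14.1% and 16S genes 2.85% against 4.18%, while 5S genes held 13.8% against 10.7%. A lower level of most transcripts per cell was not tested, as the data give shares of a library.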
